A study of Mus musculus with 2 samples.

How the data were processed

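Limbs of B6NCrl mouse embryos at 12.5 days were collected in pools of 88 embryos (replicate 1) and 68 embryos (replicate 2), and 10 ng of RNA per library was used for oligo-dT primed cDNA with ERCC spike-in RNA, per the labels' protocols. The replicate numbers come from the labels, which name them biological replicates of 1 tissue and age. No second group was given, so the p-values compare 2 libraries and not conditions.

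Expected counts per gene and transcript were estimated by the authors and deposited, in columns laid out as RSEM writes them, and they need not be whole numbers. The authors normalized these values for effective length and depth to TPM, the deposited unit on which levels are reported. FPKM per gene was also deposited by the authors and was used here only as an alternative. The transcript tables deposited by the authors hold each transcript's percent of its gene. Each library was quantified by the authors with GENCODE M21 and with GENCODE M4 on mm10, per the labels, and M21, the later annotation, was the main one by a rule fixed before the data were examined. The aligner, the version of the estimating program and the use of strand were not given in the sources used here. The deposited M21 tables hold 55536 gene entries, 26248 tRNA entries and 97 spike-in or control entries, 96 of them ERCC. The effective length in the tables is the length less 99 nt, so TPM of very short entries rests on few reads. Deposited TPM covers all entries, and spike-ins held 7.34% of it in replicate 1 and 5.13% in replicate 2. Gene symbols, types and coordinates come from the GENCODE M21 annotation, in which all 55536 gene IDs of the M21 tables were found.

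Totals of expected counts over genes were 29633457 and 30118921. These depths give 37.5 and 37.9 reads for a transcript of 2000 nt at 1 TPM, and a gene with 0 reads was given the limit of 3 reads. tRNA and spike-in entries were left out of the library sizes and of the counts of genes.

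Genes at 1 TPM in both libraries were counted. Agreement was described by Pearson and Spearman coefficients of log2(TPM + 1) across genes at a mean of 1 TPM and by the common biological coefficient of variation from edgeR 4.0.16 on rounded expected counts with an intercept-only design. A coefficient from 2 libraries is imprecise. Differing genes were called by an exact two-sided binomial test on rounded expected counts with edgeR TMM library sizes, adjusted by Benjamini-Hochberg, at an adjusted p under 0.05 and at least a 2-fold TPM ratio. Printed log2 ratios are on the log2(TPM + 1) scale, which understates changes of low genes, unless said otherwise. Lists with 5 or more members at a mean of 1 TPM were compared by the percentile of their median log2 ratio among 10000 random lists matched in 20 bins of mean TPM. Percentiles under 2.5 or over 97.5 were called outside the middle 95%. For gene pairs, the smaller of the 2 absolute log2 TPM ratios was compared with the 95th percentile of the absolute log2 difference of the 500 genes nearest in level. Transcript shares were computed as percent of the summed TPM of a gene's transcripts.

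The 32 lists, the 22 pairs and the rule for named genes were fixed at the same time. The rule took the 10 most abundant nuclear genes, 2 to 4 of the most abundant members of each list, in most lists its lowest member, all members of pairs, and the 10 called genes per direction with the largest ratios at a mean of 5 TPM. It also took the 10 most abundant list genes with a second transcript of at least 25%, and the 5 list genes per direction that differed most between annotations. Genes named outside this rule were chosen after their values were seen, namely Akt1 and 3 of the called list genes in the report, and other genes in the closing section. Of 449 listed symbols, 448 were found.

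The tests of differing genes and of lists were tested on simulated data, and the functions for transcript shares, the spread of pairs and the comparison of annotations on small tables with known answers. With 200 changed genes at a mean of 5 TPM or more among 15926 genes drawn on real means and the coefficient of variation above, the test of differing genes recovered 99.0% of 102 genes changed 3-fold and 99.0% of 98 genes changed 5-fold, and called 19 of 15726 unchanged genes. With changed genes under 5 TPM, 83 of 101 changed 3-fold and 89 of 99 changed 5-fold were recovered. In the test of lists over the same number of genes, 199 of 200 random lists of 15 genes shifted by 0.25 on the log2 scale lay outside the middle 95%. Of 200 random lists left as they were 11 did, a share that the construction sets near 5% and that does not cover lists whose genes vary together. Alternatives tried were other minima of TPM, pseudocounts, library scalings with DESeq2 1.42.0 and total counts, the M4 quantification, FPKM, TPM rescaled without the mitochondrial genome and spike-ins, counts without length, list means, length matching, corrections for GC content and length, and either library alone. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3, and matplotlib 3.10.9 for figures.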

Results

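RNA from limbs of B6NCrl mouse embryos at 12.5 days of development was sequenced as polyA plus RNA after oligo-dT priming, in 1 group of 2 biological replicates. Replicate 1 was a pool of 88 embryos and replicate 2 a pool of 68 embryos, of both sexes, and each library was made from 10 ng of RNA with ERCC spike-in RNA added. Values are TPM (transcript abundance normalised for length and depth) as the authors deposited them for the GENCODE M21 annotation on mm10, given as mean ± SD over n = 2 libraries unless stated. The expected counts of genes summed to 29633457 in replicate 1 and 30118921 in replicate 2, so that a transcript of 2000 nt at 1 TPM rested on 37.5 and 37.9 reads. Spike-in entries took 3.19% of the reads of replicate 1 and 2.24% of those of replicate 2. With a single group no conditions were compared, and the differences described are between these 2 libraries or between genes.

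A total of 15181 genes reached 1 TPM in both libraries, 12802 of them protein-coding, 322 annotated as lincRNA and 564 as processed pseudogenes. The counts per library were 15818 in replicate 1 and 15964 in replicate 2, and 1702 genes reached 100 TPM in both. With the M21 annotation the most abundant nuclear gene was Actb (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754), which encodes cytoplasmic beta-actin, at 10302 ± 701 TPM. It was followed by Rn7s1 and Rn7s2, annotated copies of the signal recognition particle RNA, each listed at 9392 ± 469 TPM with identical values in each library. The ribosomal RNA entry CT010467.1 stood at 8259 ± 542 TPM, the embryonic beta-globin Hbb-y at 7124 ± 2.38 TPM, the histone gene Hist1h2ap at 5287 ± 554 TPM and the adult alpha-globin Hba-a2 at 5244 ± 27.6 TPM. Gm28437, an annotated pseudogene on chromosome 1, stood at 5018 ± 52.7 TPM, the nuclear RNA Malat1 at 4699 ± 701 TPM and the prolyl isomerase gene Ppia at 4529 ± 229.6 TPM. Levels of Rn7s1, Rn7s2, Hist1h2ap, Hba-a2 and Gm28437 are uncertain because near-identical copies can share their reads. How far oligo-dT priming kept the RNAs of CT010467.1, Rn7s1, Rn7s2 and Hist1h2ap in proportion to the tissue was not tested. The level of Actb is uncertain too, since 54.5% ± 2.26 of it lay in a noncoding entry of 241 nt, and with the M4 annotation Actb stood at 5397 ± 154 TPM and ranked 6th among nuclear genes. Entries of the mitochondrial genome held 1.17% of gene reads in replicate 1 and 1.07% in replicate 2, and globin genes 0.605% and 0.596%. All 13 mitochondrial protein-coding genes reached 1 TPM, led by mt-Atp6 at 5008 ± 338 TPM and mt-Atp8 at 3956 ± 66.6 TPM, with mt-Nd4l lowest at 43.0 ± 2.09 TPM.

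Genes that mark the limb field and its mesenchyme were detected throughout: all 26 listed genes reached 1 TPM in both libraries, with a median of 31.7 TPM. The homeobox gene Msx1 (ENSMUSG00000048450.10, chromosome 5, 37820485 to 37824583) was the most abundant at 375 ± 19.6 TPM, ahead of the paired-related homeobox genes Prrx1 at 157 ± 3.34 TPM and Prrx2 at 156 ± 6.04 TPM and the hindlimb factor Pitx1 at 149.8 ± 20.1 TPM. The zinc-finger gene Sall3 was lowest at 2.20 ± 0.0566 TPM. The forelimb factor Tbx5 stood at 34.2 ± 8.19 TPM and the hindlimb factor Tbx4 at 32.9 ± 3.18 TPM. The proximal marker Meis2 stood at 17.7 ± 1.88 TPM and Msx2, a paralogue of Msx1, at 53.8 ± 5.12 TPM.

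The 4 Hox clusters, which pattern the body and limb axes, differed widely in level. In the Hox A cluster 9 of 11 genes reached 1 TPM in both libraries, led by Hoxa10 at 223 ± 15.4 TPM, Hoxa11 (chromosome 6, 52242106 to 52245810) at 73.1 ± 5.88 TPM and Hoxa9 at 60.1 ± 2.39 TPM, while the digit-region gene Hoxa13 stood at 26.5 ± 0.990 TPM and Hoxa4 was lowest at 0.490 ± 0.297 TPM. In the Hox D cluster 7 of 9 genes did so, led by Hoxd12 at 95.8 ± 10.8 TPM, Hoxd13 (ENSMUSG00000001819.4, chromosome 2, 74668310 to 74671599) at 67.0 ± 4.48 TPM and Hoxd11 at 46.3 ± 4.36 TPM, with Hoxd1 lowest at 0.330 ± 0.0141 TPM. All 9 Hox C genes reached 1 TPM, from Hoxc10 at 16.5 ± 0.516 TPM and Hoxc5 at 7.28 ± 3.19 TPM down to Hoxc12 at 1.92 ± 0.481 TPM. Only 2 of the 10 Hox B genes, Hoxb2 at 4.38 ± 0.516 TPM and Hoxb7 at 1.52 ± 0.127 TPM, did so in both libraries, and Hoxb13 was represented by 0 reads in replicate 1 and 1 read in replicate 2.

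**Figure D1:**
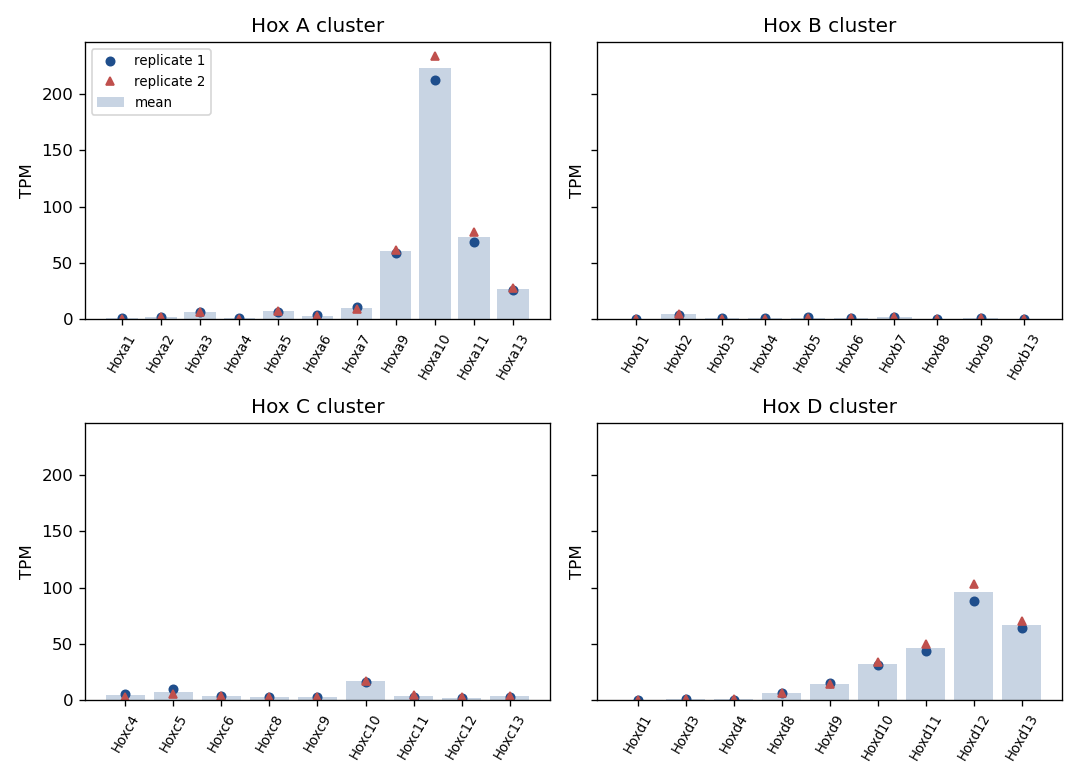
TPM of each gene of the 4 Hox clusters (horizontal axis, cluster order by number) as the mean of the 2 limb libraries (bar) and as each replicate (circle, replicate 1, and triangle, replicate 2). Hoxa10 is the tallest at 212 and 234 TPM, and no Hox B gene passes Hoxb2 at 4.02 and 4.75 TPM.

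Of the 13 hedgehog pathway genes 12 reached 1 TPM in both libraries, led by the surface protein genes Gas1 at 262 ± 11.9 TPM and Smo at 51.3 ± 6.34 TPM and the transcription factor gene Gli3 at 41.0 ± 1.61 TPM. The response gene Gli1 stood at 9.93 ± 1.65 TPM and the cartilage ligand gene Ihh at 3.87 ± 1.70 TPM. The limb bud ligand gene Shh (ENSMUSG00000002633.4, chromosome 5, 28456815 to 28467256) had 4 reads in replicate 1 and 3.36 expected reads in replicate 2, or 0.0650 ± 0.00707 TPM, where 3 reads would correspond to 0.0553 and 0.0548 TPM. In the list of the apical ridge, the epithelial rim that signals to the limb bud, 14 of 16 genes reached 1 TPM in both libraries, with Dlx5 at 30.1 ± 4.32 TPM, Trp63 at 21.9 ± 3.15 TPM and Fgf8 at 13.6 ± 1.06 TPM, and Fgf4 lowest at 0.385 ± 0.00707 TPM. All 16 epithelial genes reached 1 TPM, led by the keratin genes Krt14 at 119.9 ± 7.21 TPM and Krt5 at 82.9 ± 3.12 TPM, with Tfap2c lowest at 3.50 ± 0.127 TPM. All 23 genes of the BMP and interdigit list did too, led by the BMP-response genes Id3 at 517 ± 10.7 TPM, Id2 at 293 ± 5.95 TPM and Id1 at 248 ± 21.1 TPM, with the BMP antagonist gene Grem1 lowest at 2.71 ± 0.368 TPM.

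Genes of the cartilage list were more often detected than those of hypertrophic cartilage and bone. Of 20 cartilage genes 19 reached 1 TPM in both libraries, led by the type II collagen gene Col2a1 (ENSMUSG00000022483.17, chromosome 15, 97975602 to 98004695) at 385 ± 57.7 TPM, the ubiquitin ligase gene Wwp2 at 222 ± 1.55 TPM (108 ± 1.80 with M4, below Sox9) and the cartilage factor Sox9 at 196 ± 1.40 TPM, and Snorc was lowest at 2.54 ± 2.47 TPM. Of 15 genes of hypertrophic cartilage and bone 9 did so, led by the parathyroid hormone receptor gene Pth1r at 62.5 ± 1.94 TPM and Mef2c at 49.9 ± 0.113 TPM (22.6 ± 2.45 with M4). The bone factors Runx2 and Sp7 stood at 7.94 ± 1.88 and 2.92 ± 0.587 TPM, the hypertrophic collagen gene Col10a1 at 0.390 ± 0.0849 TPM, and Bglap2 had 0 reads in both libraries, which allows up to 0.409 and 0.404 TPM. The joint list had 11 of 12 genes at 1 TPM in both, led by Sfrp2 at 243 ± 3.21 TPM and Jun at 73.9 ± 4.45 TPM, with the joint marker Gdf5 at 49.5 ± 4.46 TPM and Wnt16 lowest at 0.945 ± 0.00707 TPM. The tendon and connective tissue list had 19 of 20, led by the collagen genes Col3a1 at 692 ± 4.32, Col1a2 at 363 ± 7.49 and Col1a1 at 253 ± 30.4 TPM, with Egr2 lowest at 0.170 ± 0.0283 TPM.

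Listed genes of muscle and of other cell types were detected as well. From bulk RNA it cannot be told which cells expressed them, and whether the genes named are specific to these cell types was not tested. The muscle progenitor list had 15 of 16 genes at 1 TPM in both libraries, led by the myogenic factor Myog at 89.6 ± 4.64 TPM, with Myod1 at 39.7 ± 2.77 TPM, while Pax3 stood at 1.32 ± 0.113 TPM and Pax7 was lowest at 0.335 ± 0.0212 TPM. The muscle fibre list had 19 of 20, led by cardiac actin Actc1 at 326 ± 10.1 TPM, Tnnt1 at 150.3 ± 2.86 TPM and Myl1 at 134 ± 1.15 TPM, with skeletal actin Acta1 at 87.7 ± 8.76 TPM, the embryonic myosin Myh3 at 40.05 ± 3.75 TPM, the perinatal myosin Myh8 at 5.57 ± 0.368 TPM and the creatine kinase gene Ckm lowest at 0.265 ± 0.0919 TPM. All 14 red blood cell genes that were found did so, with the adult globins Hba-a1 at 2456 ± 69.6 TPM and Hbb-bs at 547 ± 40.5 TPM, the embryonic alpha-globin Hba-x at 1241 ± 34.1 TPM and the erythroid factor Gata1 lowest at 1.68 ± 0.198 TPM. All 15 endothelial genes did, led by Egfl7 at 62.9 ± 1.71 TPM and Plvap at 48.0 ± 2.57 TPM, with Sox17 lowest at 6.37 ± 0.233 TPM. All 15 macrophage genes did, led by Pf4 at 43.0 ± 0.240 TPM and C1qb at 15.2 ± 1.55 TPM, with Ptprc lowest at 1.14 ± 0.198 TPM. The Schwann cell and melanoblast list had 10 of 12, led by Ets1 at 38.0 ± 1.00 TPM and Ngfr at 20.1 ± 1.04 TPM, with Foxd3 lowest at 0.695 ± 0.0212 TPM. The pericyte and smooth muscle list had 6 of 10, led by Acta2 at 101 ± 7.9974 TPM and Pdgfrb at 42.4 ± 3.46 TPM, with Myh11 lowest at 0.165 ± 0.00707 TPM.

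A minority of the listed markers of neurons and of other organs reached 1 TPM. Of 14 neuron and neural tube genes 5 reached 1 TPM in both libraries, led by Tubb3 at 9.32 ± 3.10 TPM, Dcx at 7.62 ± 0.728 TPM and Stmn2 at 7.22 ± 2.21 TPM. The liver list had 3 of 10, led by the fetal serum protein gene Afp at 3.16 ± 1.15 TPM and Apoa1 at 2.23 ± 0.361 TPM, with Fgb lowest at 0.0350 ± 0.00707 TPM. The heart list had 3 of 10, led by Myh6 at 1.99 ± 0.827 TPM (0.555 ± 0.163 with M4) and Myl3 at 1.67 ± 0.573 TPM, and Nkx2-5 had 0 reads, which allows up to 0.113 and 0.112 TPM. In the gut, lung and kidney list only Six2 did, at 9.21 ± 0.813 TPM, next came Wt1 at 0.515 ± 0.177 TPM, and the gut factor Cdx2 had 0 reads, which allows up to 0.0703 and 0.0696 TPM. Floors and counts cover counting error only, and molecular identifiers are not given in the sources used here.

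Genes of the cell cycle were detected throughout. All 15 S phase genes reached 1 TPM in both libraries, led by the nucleotide synthesis genes Rrm2 at 300.4 ± 19.4 TPM and Tyms at 276 ± 8.29 TPM, with Cdc6 lowest at 36.8 ± 1.49 TPM. All 15 genes of G2 and mitosis did, led by Ube2c at 457 ± 29.7 TPM and Cdk1 at 352 ± 8.82 TPM, with Cenpe lowest at 31.3 ± 0.311 TPM. The immediate early and heat shock list had 13 of 15, led by Ier2 at 109.8 ± 7.43 TPM, with Hspa1b lowest at 7.98 expected reads in replicate 1 and 0 in replicate 2. The hypoxia and glycolysis list had 12 of 14, led by the glycolytic genes Eno1 at 1447 ± 65.1 TPM and Ldha at 1264 ± 46.2 TPM, with the carbonic anhydrase gene Car9 lowest at 0.930 ± 0.113 TPM. All 15 imprinted genes did, led by Mest at 1199.6 ± 104 TPM, Cdkn1c at 1116 ± 32.6 TPM and Igf2 at 691 ± 58.6 TPM, with H19 at 483 ± 55.7 TPM and Rtl1 lowest at 1.29 ± 0.141 TPM. The Y-linked Eif2s3y stood at 31.9 ± 0.919 TPM and Ddx3y at 22.9 ± 0 TPM, with Kdm5d lowest at 10.4 ± 0.0141 TPM, and the X-inactivation RNA Xist stood at 22.9 ± 0.0424 TPM. All 15 housekeeping genes did, with Eef1a1 at 3288 ± 20.7 TPM and Polr2a lowest at 25.7 ± 5.75 TPM. Across the 32 lists, 379 of the 448 genes found reached 1 TPM in both libraries.

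Ratios between functionally paired genes were compared with the spread between the libraries, and 19 of 22 fixed pairs kept their direction in both libraries by more than that spread. The digit-region gene Hoxd13 exceeded Hoxd11 1.45-fold, whereas Hoxa11 exceeded Hoxa13 2.75-fold. Gli3 exceeded Gli1 4.16-fold and Sox9 exceeded Runx2 25.1-fold and Gdf5 3.97-fold. Col2a1 exceeded Col1a1 1.52-fold and Col10a1 993-fold, the latter resting on 20 and 27 reads of Col10a1. Runx2 exceeded Sp7 2.70-fold, Myog exceeded Myod1 2.26-fold, Myh3 exceeded Myh8 7.18-fold and Actc1 exceeded Acta1 3.72-fold. Embryonic Hbb-y exceeded adult Hbb-bs 13.0-fold, while adult Hba-a1 exceeded embryonic Hba-x 1.98-fold, although reads of Hba-a1 can be shared with Hba-a2. Fgf8 exceeded Fgf4 35.2-fold, Ihh exceeded Shh 56.7-fold on 4 and 3.36 reads of Shh, Msx1 exceeded Msx2 6.98-fold and Igf2 exceeded H19 1.43-fold. Pitx1 exceeded Tbx5 4.43-fold. Hoxa13 exceeded Meis2 1.5017-fold, which no longer passed the spread with expected counts not divided by length (log2 ratio 0.11). The same counts moved 5 other ratios by over 1.5 times while each still passed the spread, from mean log2 ratios of 5.14 to 3.41 for Fgf8/Fgf4, 2.06 to 2.88 for Gli3/Gli1, 1.99 to 2.85 for Sox9/Gdf5, 9.96 to 10.56 for Col2a1/Col10a1 and -2.15 to -1.54 for Tbx5/Pitx1.

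The 3 pairs that did not pass were Tbx5/Tbx4, Prrx1/Prrx2 and Pax3/Pax7. The log2 ratio of Tbx5 over Tbx4 was 0.39 and -0.31 in replicates 1 and 2, opposite in sign, against a spread of 0.30. For Prrx1 over Prrx2 the ratios were 0.07 and -0.05, also opposite in sign, against 0.21, and for the muscle progenitor factors Pax3 over Pax7 they were 2.00 and 1.95 against 2.12. The spread was the 95th percentile of the absolute log2 difference between the libraries over the 500 genes nearest in level to the lower gene of the pair, because an exact permutation test of 2 values against 2 cannot give a two-sided p under 0.333. With expected counts not divided by length, Prrx1 over Prrx2 passed the spread, with a mean log2 ratio of 2.22.

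**Figure D2:**
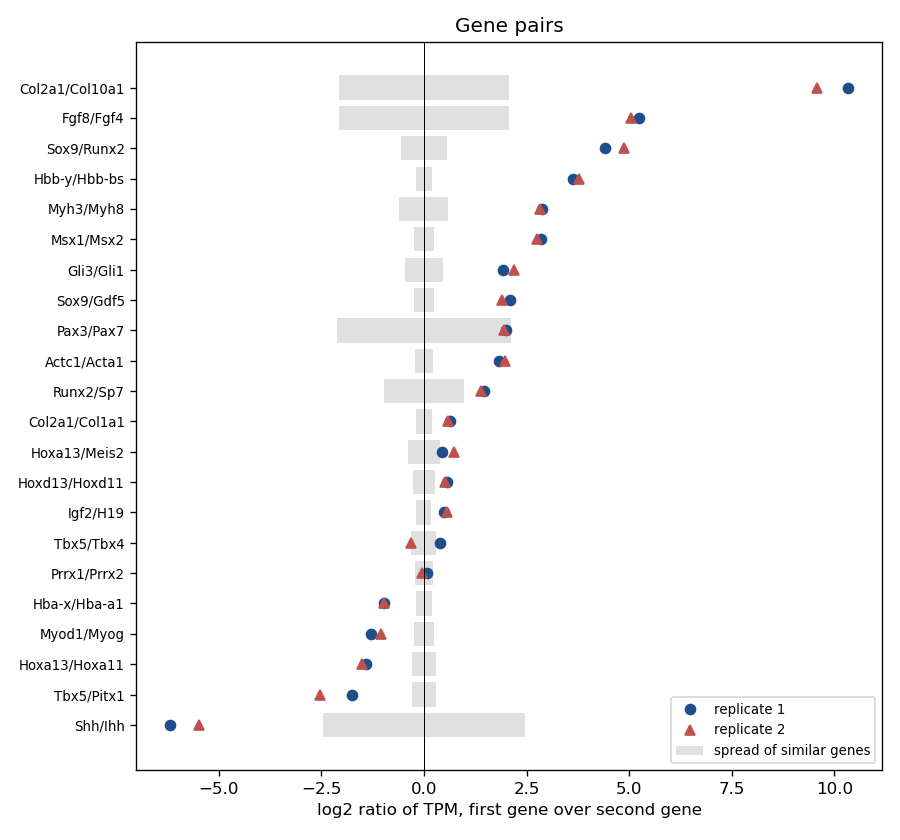
Log2 ratio of TPM of the first gene over the second for each fixed pair in replicate 1 (circles) and replicate 2 (triangles), with the 95th percentile spread of genes of similar level as a grey bar on both sides of 0. The Tbx5/Tbx4 markers fall on opposite sides of 0, at 0.39 and -0.31.

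The 2 libraries were compared to see which genes differed between the pools. Across 15926 genes at a mean of 1 TPM or more, log2(TPM + 1) had a Pearson r of 0.986 and a Spearman rho of 0.986, computed across genes, which are not independent replicates. The median absolute log2 difference was 0.10, and it fell with level from 0.20 for genes at 1 to 5 TPM to 0.06 for genes at 100 TPM and over. The common biological coefficient of variation by edgeR was 7.19%.

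Matn1, Kera and Acan were among the genes lower in replicate 2, and Adnp, Cdk2ap1 and Selenon among those higher. By an exact binomial test on rounded expected counts, 163 of 15926 genes differed at an adjusted p under 0.05 and at least 2-fold in TPM, 67 higher in replicate 1 and 96 higher in replicate 2. Matn1 (ENSMUSG00000040533.7, chromosome 4, 130944385 to 130955475), which encodes the cartilage matrix protein matrilin 1, stood at 24.0 and 9.65 TPM in replicates 1 and 2 (log2 ratio -1.23, exact binomial adjusted p = 1.84e-51). The proteoglycan genes Kera and Acan stood at 27.6 and 12.8 TPM and at 8.07 and 3.90 TPM, with log2 ratios of -1.05 and -0.89 on the log2(TPM + 1) scale. Acan was not past the 99th percentile of the difference of genes of similar level. The other 5 genes higher in replicate 1 at a mean of 5 TPM or more were Gm26602, Snora73b, Gm15421, Gm43126 and Gm10698, with log2 ratios from -1.69 to -1.09 (-2.34 for Gm26602 with M4). Gm26602 is a protein-coding entry of 285 nt, Snora73b a small nucleolar RNA, Gm43126 an antisense RNA, and Gm15421 and Gm10698 are processed pseudogenes, so that their levels are uncertain.

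In the other direction Adnp (ENSMUSG00000051149.15, chromosome 2, 168180986 to 168207112), which encodes a homeobox protein, stood at 4.77 and 20.7 TPM in replicates 1 and 2 (log2 ratio 1.91, exact binomial adjusted p = 6.90e-196). Cdk2ap1 (chromosome 5, 124345417 to 124363082), which encodes a CDK2-associated protein, stood at 53.4 and 174 TPM, the selenoprotein gene Selenon (chromosome 4, 134537892 to 134552166) at 11.5 and 38.0 TPM, Eid2 at 4.19 and 15.1 TPM, and the G protein subunit gene Gna12 (chromosome 5, 140758408 to 140830431) at 14.4 and 39.6 TPM. The log2 ratios of these 4 genes ran from 1.68 for Cdk2ap1 to 1.40 for Gna12. Expected counts were 305 and 1563 for Adnp and 1217 and 3831 for Cdk2ap1 in replicates 1 and 2. The Xist antisense RNA Tsix stood at 2.09 and 8.85 TPM (log2 ratio 1.67, and 0.99 with M4), but reads of overlapping antisense genes cannot be told apart where use of strand is not given. Hist1h2aj, Gm42845, Gm49550 and Gm12184 complete the 10 genes with the largest ratios, of which the first 3 are annotated as pseudogenes and Gm12184 as protein-coding, and their levels are uncertain where reads are shared with similar loci. Hist1h2aj had 0 reads in replicate 1 and 324 in replicate 2. Gm42845, an entry of 105 nt, rested on only 1.24 and 16.1 expected reads in replicates 1 and 2, and Gm49550 on 7.02 and 32.6. The test covers counting error and compares these libraries, not conditions, and at a mean of 5 TPM or more the count was 36 genes, 28 of them higher in replicate 2.

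**Figure D3:**
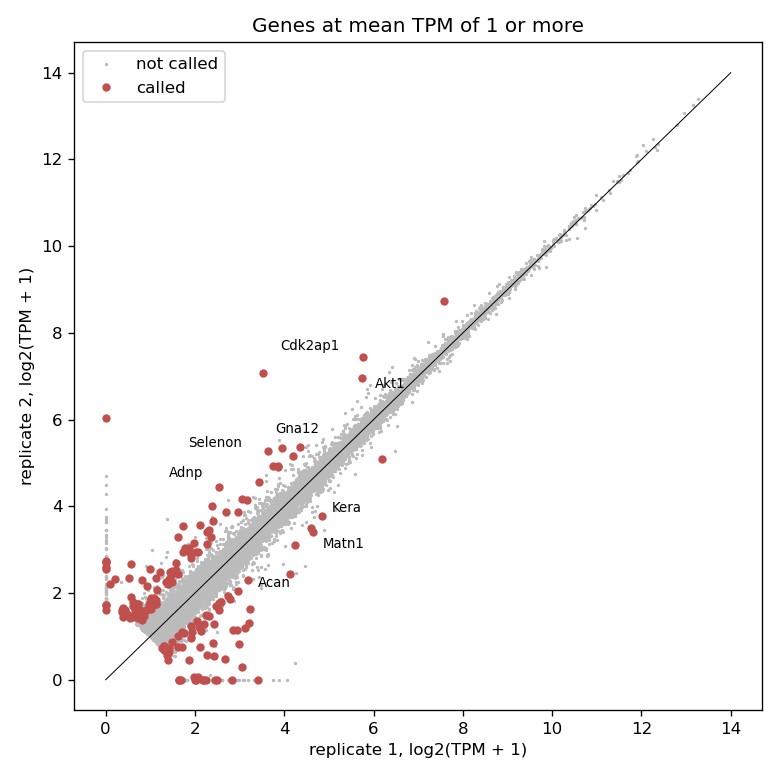
Log2(TPM + 1) of each gene at a mean of 1 TPM or more in replicate 1 (horizontal) and replicate 2 (vertical), with the 163 genes called different in red, other genes in grey and the line of equality. Adnp, Selenon, Gna12, Akt1 and Cdk2ap1 lie above the line, and Matn1, Kera and Acan below it.

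Several lists were lower in replicate 2 as groups, among them those of cartilage and of tendon and connective tissue. In the cartilage list 18 of 20 members were lower in replicate 2 and 2 were higher, with a median log2 ratio of -0.38, at percentile 0 of 10000 random lists matched on level. Col2a1 stood at 426 and 344 TPM in replicates 1 and 2, whereas Wwp2 stood at 223 and 221 and Sox9 at 197 and 195 TPM. In the tendon and connective tissue list 19 of 19 members were lower, with a median of -0.23 at percentile 0. Col1a1 there stood at 274 and 231 TPM. In the hedgehog list 11 of 12 were lower (median -0.23, percentile 0), with Gli1 at 11.1 and 8.76 and Ihh at 5.07 and 2.66 TPM. Muscle fibre genes were lower in 15 of 19 (median -0.11, percentile 0.0200), imprinted genes in 12 of 15 (median -0.12, percentile 0) and mitochondrial genes in 11 of 13 (median -0.12, percentile 0).

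Neuronal genes were shifted the other way, with 4 of 5 higher in replicate 2, a median of 0.56 and percentile 99.95, while Dcx was the member that was lower. Tubb3 stood at 7.13 and 11.5 TPM and Stmn2 at 5.66 and 8.79 TPM in replicates 1 and 2. The lists of hypertrophic cartilage and bone (median -0.22, percentile 0.520), macrophages (-0.16, percentile 0.450), pericytes and smooth muscle (-0.16, percentile 1.24), the apical ridge (-0.13, percentile 2.04) and red blood cells (-0.05, percentile 2.20) were also lower in replicate 2. In all, 12 of 28 lists lay outside the middle 95%, where about 1 in 20 would by chance if members varied independently. The 5 lists named last and the neuronal list returned inside it when the mean of the list replaced the median, although 3 of the 6 means were larger in size than the medians. The means were -0.27 (percentile 4.09) for hypertrophic cartilage and bone, -0.12 (8.17) for macrophages, -0.18 (4.53) for pericytes and smooth muscle, -0.09 (13.85) for the apical ridge, -0.06 (11.94) for red blood cells and 0.50 (97.42) for neurons. After a correction for GC content the apical ridge and red blood cell lists lay just inside it, at percentiles 2.70 and 2.85, although their medians of -0.14 and -0.06 were no closer to 0. With scaled counts the red blood cell list also lay just inside, with a median of -0.05 at percentile 2.94.

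The other 16 lists lay inside the middle 95%. They included S phase (median 0.05, percentile 72.3), G2 and mitosis (0.02, 35.7), the housekeeping genes (0.02, 41.3), the BMP and interdigit list (0.01, 43.8), the joint list (0.03, 63.2) and the limb field and mesenchyme (0.05, 90.6). The Hox A, C and D clusters had medians of 0.07, 0.01 and 0.11 at percentiles 86.0, 55.1 and 95.8. The epithelial list (-0.08, percentile 2.64), muscle progenitors (-0.08, 5.08), endothelium (-0.06, 9.85), Schwann cells and melanoblasts (0.06, 78.4), immediate early and heat shock genes (-0.06, 10.2), hypoxia and glycolysis (0.03, 49.0) and the X-inactivation and Y-linked genes (0.00, 53.2) completed them. Of the 382 list genes tested, 166 had an adjusted p under 0.05 by the exact binomial test over all genes and 185 when adjusted over the list alone, and 8 passed the 2-fold criterion as well under either adjustment. Among all 15926 genes 3022 had an adjusted p under 0.05, as the test allows for counting error only. These 8, of which Comp, Wnt4 and Fabp7 are outside the rule for named genes and were chosen after their values were seen, were Hoxb5, Matn1, Acan, Comp, Snorc, Wnt4, Fabp7 and Nefl.

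**Figure D4:**
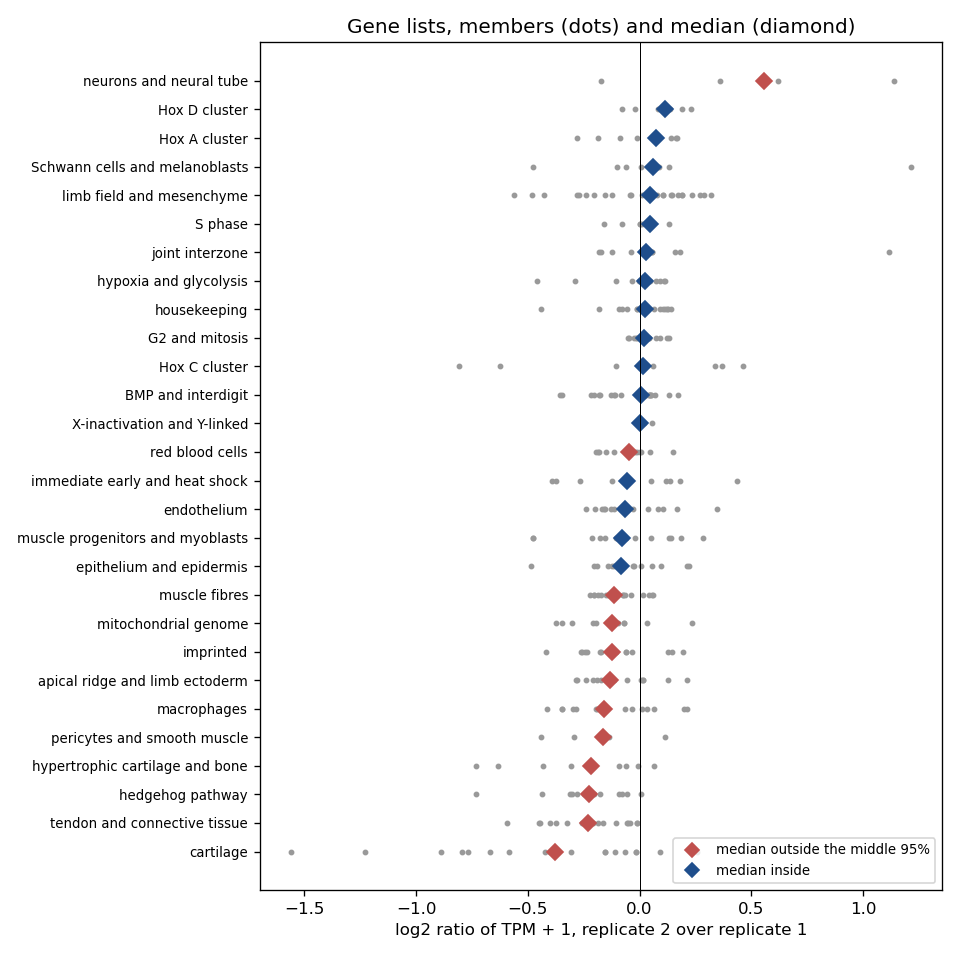
Log2 ratio of (TPM + 1) in replicate 2 over replicate 1 for the members (dots) and the median (diamonds) of each of the 28 lists tested, with medians outside the middle 95% of matched random lists in red and the others in blue. The cartilage median lies lowest at -0.38 and the neuronal median highest at 0.56.

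Transcript shares were compared for 9970 genes at 5 TPM or more with several annotated transcripts, and the second transcript held at least 25% of the gene's TPM in both libraries for 2247 of them. The leading transcript by mean share was annotated as protein-coding in 87.6% of the 9970 genes. TPM divides reads by effective length, so a short entry holds a larger share of a gene's TPM than of its reads. Shares of reads were not computed. For Actb the largest share belonged to a noncoding entry of 241 nt, with 54.5% ± 2.26 of the gene's TPM, ahead of a protein-coding transcript of 1920 nt with 45.2% ± 2.21. Gapdh followed the same order, with 62.3% ± 2.56 for a noncoding entry of 483 nt and 35.1% ± 1.08 for a coding transcript of 1420 nt. Hba-a1 was led by a retained-intron entry of 494 nt with 73.3% ± 1.93, over 26.7% ± 1.93 for its coding transcript. The leading transcript of Igf2 was a noncoding entry of 958 nt with 37.1% ± 0.992, ahead of a coding transcript of 650 nt with 31.4% ± 0.810. H19 was led by entries of 2286 and 1178 nt with 36.9% ± 0.0281 and 33.8% ± 1.05, and Tyms by 2 entries annotated as targets of nonsense-mediated decay with 35.5% ± 1.48 and 25.6% ± 0.267. Among genes led by coding transcripts, the leading pair held 33.2% ± 0.539 and 27.8% ± 1.64 for Prrx1, 34.5% ± 0.278 and 29.1% ± 1.46 for Tnnt1, and 61.0% ± 4.53 and 35.5% ± 5.10 for Myl1. For Slbp the shares were 46.0% ± 2.75 and 42.9% ± 2.43, and the order of these transcripts differed between the libraries. The order of the 2 transcripts with the highest mean shares differed between the libraries in 721 genes. The share of the leading transcript by mean differed by a median of 3.08 percentage points.

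The authors' other quantification of the same reads, on GENCODE M4, was compared gene by gene with the M21 values. The Spearman rho of TPM across 15157 genes, which are not independent replicates, was 0.982 on average over the libraries, and 383 genes differed at least 2-fold in TPM + 1 in both libraries, 243 higher with M21 and 140 lower. Of the 10 list genes named by the fixed rule as differing most, 4 were among these, Sox6, Wwp2, Mef2c and Ndn, and the other 6 differed by less than 2-fold in at least 1 library. The cartilage factor Sox6 stood at 66.9 ± 8.58 TPM with M21 and 17.5 ± 2.10 TPM with M4, Wwp2 at 222 ± 1.55 and 108 ± 1.80, Mef2c at 49.9 ± 0.113 and 22.6 ± 2.45, Actb at 10302 ± 701 and 5397 ± 154 and the sarcomere gene Myom1 at 6.42 ± 0.474 and 3.08 ± 0.0707. In the other direction the imprinted gene Ndn stood at 70.0 ± 1.11 TPM with M21 and 171 ± 2.31 TPM with M4, Peg10 at 8.09 ± 1.15 and 13.0 ± 0.933, Dnajb1 at 55.8 ± 3.25 and 78.2 ± 4.78, Zfp36 at 5.84 ± 0.247 and 8.42 ± 0.311, and the hedgehog antagonist Hhip at 3.52 ± 0.955 and 5.17 ± 1.34. For these genes the gap between annotations exceeded the SD between the libraries.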

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

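The tests of the cell share, of embryo age, of the hindlimb share, of proximal tissue, of isoforms and of shared reads were chosen only after the results they measure were seen, and the GC and length corrections were added after seeing the data. A further test, of TPM differences without a count difference, was dropped once counts were seen to move with TPM. The tRNA entries, which the comparisons did not use, held 36 reads in replicate 1 and 41.8 expected reads in replicate 2, spread over 4 and 9 of 26248 entries. They stand here because reads fell on entries that no comparison used: both sums exceed the 3 reads that a sum of 0 allows, as did 4 single entries in each library.

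The cartilage list was lower in replicate 2. Corrections for a trend over GC content and over gene length left its median log2 ratio at -0.40 and -0.37, both at percentile 0, and the trends themselves ran only from -0.01 to 0.04 and from -0.02 to 0.09, which argues against either as the whole cause. A smaller share of the same cartilage cells would lower alike those members that are expressed in cartilage alone. Of the 20 members 11 lay farther from the list's median than the spread of similar genes. Snorc, Matn1, Acan and Col11a2 lay below it, and Sox5, Sox6, Sox9, Wwp2 and the 3 type IX collagen genes above. The Sox genes are also expressed outside cartilage. Expression of the other members there was not tested, so the count of 11 cannot decide on the cell share. Whether the replicate 2 pool was younger or less differentiated stays open, although the bound set for it, a muscle fibre list under percentile 2.5, was met at 0.02, and it was set aside only after all values were known. The neuronal list was high, at 99.95. The mitochondrial, imprinted and macrophage lists were low too, at 0, 0 and 0.45, with muscle progenitors at 5.09. Whether these lists follow embryo age was not tested.

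The forelimb markers Tbx5, at 39.96 and 28.4 TPM in replicates 1 and 2, and Hoxc5, at 9.53 and 5.02 TPM, and the hindlimb markers Pitx1, at 135.6 and 164 TPM, and Isl1, at 6.94 and 13.3 TPM, each differed by more than the spread of similar genes, whereas Hoxc4, Tbx4, Hoxc10, Hoxc11, Hoxc12, Hoxc13 and Hotair were within it. Among the markers within the spread, Hoxc4 was lower in replicate 2, with a log2 TPM ratio of -0.782 against a spread of 0.785. The others within it were all higher in replicate 2, from 0.06 for Hoxc10 to 0.60 for Hoxc11. A larger hindlimb share in the replicate 2 pool could not be settled, because the median of Hoxc12, Hoxc13 and Hotair lay at percentile 92.975 of random trios, inside the middle 95%. Less proximal tissue could not be settled either, at percentile 3.205 for Meis1, Meis2 and Irx3. Both bounds replaced earlier ones after these values were known: the first wording asked for directions only, and the hindlimb share would have met it, as Hoxc12, Hoxc13 and Hotair were all higher and Meis1 and Meis2 not both lower, while proximal tissue would have stayed undecided. Isl1, also a gene of neurons, was added after its values were seen, and the design names no group that tests a biological explanation.

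At a mean of 5 TPM or more, 19 protein-coding genes were over 2-fold higher in replicate 2, among them Adnp, Cdk2ap1, Selenon, Akt1, Axin1 and Dvl1. The GC trend reached at most 0.04, against log2 TPM ratios of 1.01 to 2.12, which argues against it as the whole cause, and its removal left 94.7% at least 2-fold higher, as 18 of 19, with 1190002N15Rik going from 1.01 to 0.98 because it lay next to the threshold. Counts were also 2-fold higher in 100%, but the genes had been selected partly on counts, so the lengths were compared: shifts in mean transcript length would have raised the TPM ratios by at most 0.06 on the log2 scale, which argues against reads moved between isoforms of different length. With the M4 annotation 94.4% were at least 2-fold higher in TPM, as 17 of the 18 present there. This argues against sharing with loci that differ between the annotations. It cannot address reads shared with similar loci that both annotations hold, since these would act alike in both. The effect of amplification from 10 ng of RNA, of a variant or of a biological difference between the pools was not tested, and all stay open.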

How the results depend on the processing

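The added alternatives, chosen after seeing the data, are the length minimum of 300 nt, protein-coding genes only, 2-fold in scaled counts, and the GC, length and count versions of the list test. Counts of detected genes, of list genes at 1 TPM and of pairs past the spread stayed within 1.5 times of the reported counts under every alternative run. The Pearson r was 0.961 with a pseudocount of 0.1, 0.994 without a filter, 0.989 at a mean of 5 TPM or more and 0.986 with M4, against 0.986. The count of differing genes was 350 without a filter, 36 at a mean of 5 TPM, 322 by the 99th percentile of similar genes and 81 for protein-coding genes only, against 163. Of these 150, 36, 78 and 78 were among the 163, and the share higher in replicate 2 was 77.8% at a mean of 5 TPM against 58.9%. The changes without a filter, at 5 TPM and for protein-coding genes follow from testing more or fewer genes. The 99th percentile was taken from these same libraries, so a share of genes passes it by construction. A gene absent from 1 library always passes it. The 322 genes are therefore no separate measure of how many genes differ. With M4 the count was 140, of which 108 were shared. The number of lists outside the middle 95% was 6 by the mean of the list, against 12, and those 6 were among the 12. The cause was not tested. A second transcript of at least 25% was found for 1463 genes at 20 TPM, against 2247, as fewer genes were tested. The Spearman rho between annotations was 0.992 for expected counts and 0.971 at a mean of 5 TPM, against 0.982. Leaving out either replicate gave 15818 to 15964 detected genes, 380 to 385 list genes, 20 to 20 pairs, 2921 to 2949 genes with a second transcript, a rho of 0.981 to 0.982 and 432 to 451 genes over 2-fold apart. Agreement, differing genes and list differences need both libraries and have no such value. Of single values, 9 list results fell inside the middle 95% and 3 moved outside it, namely limb field and mesenchyme at a mean of 5 TPM (percentile 98.6) and Hox D (98.9) and epithelium (0.98) with scaled counts. Acan lost its call by the 99th percentile, Hoxa13/Meis2 was lost and Prrx1/Prrx2 gained with counts not divided by length. Of the 32 list medians of TPM, 19 moved by more than the SD with M4, 9 without replicate 1 and 7 without replicate 2. Rescaling TPM without the mitochondrial genome and spike-ins multiplies every gene alike, by 1.11 and 1.08 in replicates 1 and 2, so its 19 moved medians say nothing on single lists. Tbx5/Tbx4 passed the spread in each library alone, at -0.31 without replicate 1 and 0.39 without replicate 2, in opposite directions. No called value reversed its direction. No paired analysis was possible because there is only 1 group. Of genes at 1 to 5 TPM 4.88% differed at least 2-fold in TPM + 1, against 0.114% at 100 TPM and over. Depth limited the test at 1 to 5 TPM in simulated libraries, added after seeing the data. There 5.17% of unchanged genes lay at least 2-fold apart in scaled counts, and 83 of 101 genes changed 3-fold were recovered. At 4 times the depth the values were 1.87% and 93 of 101. The simulated shares use no pseudocount, so they cannot be set against the 4.88%.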

Other observations

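Genes named here were chosen after their values were seen. Spike-in reads per 100 gene reads were 3.30 in replicate 1 and 2.29 in replicate 2, and 83 of 96 ERCC sequences had at least 1 read in each library. For the 60 ERCC sequences with 10 or more reads in both libraries, the median absolute log2 ratio after scaling to the spike-in total was 0.08.

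Among the neuronal genes, the neurofilament gene Nefl stood at 3.97 and 9.95 TPM in replicates 1 and 2 and the RNA-binding protein gene Elavl4 at 2.29 and 3.22 TPM. The Schwann cell and radial glia gene Fabp7 stood at 2.30 and 6.66 TPM, while the Schwann cell gene Sox10 stood at 3.47 and 3.28 TPM. Wnt4 stood at 2.00 and 5.51 TPM, while other genes of the joint list, Gdf5 and Wnt9a, stood at 46.4 and 52.7 TPM and at 3.89 and 4.46 TPM. Among the genes over 2-fold higher in replicate 2, 6 had at least 20 reads over both libraries on coding and on retained-intron transcripts, and in 5 of them, Adnp, Akt1, Cmip, Dvl1 and Sppl3, the retained-intron ratio was the smaller. For Sppl3 the expected reads were 694 and 1673 on coding transcripts and 103.5 and 115 on retained-intron transcripts, and for Akt1 they were 2394 and 5939 on coding and 54.0 and 86.9 on retained-intron transcripts. In Dpy19l1 the retained-intron reads were 1.5 and 45.7, and the coding reads 566 and 1279. The 6 genes had been selected on a higher total in replicate 2, made up largely of coding reads in most of them. A smaller retained-intron ratio can therefore follow from the selection, and unselected genes were not compared.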
